A study of Mus musculus with 10 samples.

How the data were processed

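ATAC-seq, which reads how open chromatin is to a transposase, was made by the authors from mouse Th17 cells in 10 libraries. Naive CD4+ T cells of floxed pyruvate dehydrogenase mice with CD4-Cre (KO) or without Cre (WT) were cultured for 3 days under Th17 conditions, untreated or with 10 mM sodium acetate. The libraries fell into KO untreated (n = 3), WT untreated (n = 3), WT with acetate (n = 2) and KO with acetate (n = 2). Nothing in the labels says that replicates came from separate animals, so every p-value measures only the spread between these libraries.

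The deposited table holds 39657 sites on GRCm38, each with 1 value per library, and 38866 of them (98.0%) are 201 bp wide. Its values are signal as the authors made it: whole reads in a site divided by 1 factor per library, whose making is not given in the sources used here. Within a tolerance of 0.001 reads, 100% of the values in each library were whole multiples of 1 step. The reads behind the values were taken back from that step to give the depth, and no count test was run. Per the submitters' processing notes, the tools were FastQC 0.11.5, BWA 0.7.16a, Picard 2.10.9, Genrich, DiffBind 3.6.1, DESeq2, DESeq and deepTools 3.5.1, without the role of each. The sites are numbered as differential sites, and from this they are taken as selected on these samples. For KO against WT untreated, limma gave an unadjusted p under 0.05 at 39152 of the 39657 sites. That count does not show selection, since it was 8899 with median-of-ratios factors and 7447 with cyclic loess. Accessible sites outside the table were not analysed here. Reads in sites ranged from 3500172 to 13356560 per library, with a median of 57 to 233 reads per site.

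Column names start with ATAC1 for 5 libraries (KO untreated 1, 2 and 3, WT untreated 1 and 2) and with ATAC2 for the other 5. The columns numbered WT 4 and KO acetate 3 carry a number that the sample titles do not list, so they were placed in their group and not paired with a title. No label says that a replicate number pairs libraries across groups, and the main model held no block.

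Each site was given the protein-coding gene whose body lay nearest, within 50 kb. This gave 36441 sites (91.9%) a gene, 12219 genes in all. The gene table holds no strand, so the nearest gene body replaced the planned nearest transcription start, and a window of 1 kb around either gene end replaced promoters. A site near a gene is not known to regulate it. Sites on mitochondrial DNA (2) and on X (640) stayed in the table.

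Signal was analysed as log2(value + 1) with limma 3.58.1 (trend, robust) in R 4.3.3, with 4 group means in 1 model of all 10 libraries. The planned count test gave way to this model because the values proved to be normalized. The contrasts were KO against WT untreated, KO against WT with acetate, acetate against untreated in KO and in WT, KO with acetate against WT untreated, and the genotype by acetate interaction. P-values were adjusted by Benjamini-Hochberg over all sites, and a site was called below an adjusted p of 0.05. Library totals were compared by two-sided exact permutation tests. For gene lists, camera used a preset correlation of 0.01 and, as an alternative, an estimated correlation, adjusted over 22 lists within each contrast. Of 378 list genes 371 (98.2%) were found in the gene table and 301 had a site. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other tables and the figures.

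The 22 lists were the Th17, Th1, Th2, regulatory T cell, and naive and memory T cell programmes, T cell activation, inhibitory receptors and exhaustion, glycolysis, pyruvate dehydrogenase and TCA cycle, citrate export with acetyl-CoA and fatty acid synthesis, cholesterol synthesis, histone acetyltransferases and deacetylases, integrated stress response and amino acid supply, NRF2 and oxidative stress, interferon response, cell cycle, apoptosis, and markers of CD8 T cells, B cells, myeloid cells, NK and innate lymphoid cells, and gamma-delta T cells. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

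Genes were named by 3 parts of that rule. The first took the 10 largest rises and the 10 largest falls per comparison among called sites at or above the median of the mean log2 signal over the 10 libraries whose groups did not overlap, 1 site per gene. Chance alone leaves groups without overlap in 10% of splits for 3 against 3 libraries, 20% for 2 against 3 and 33.3% for 2 against 2. The second took fixed loci, each with all its sites and its most changed site: Pdha1, Cd4, Il17a, Il17f, Il23r, Il22, Il21, Ccr6, Ifng, Tbx21, Gata3, Foxp3, Il2ra, Tcf7, Acss2 and Acly. The third took up to 4 called members per list with the smallest adjusted p. The site named for a gene can differ between comparisons. Some results under this rule and 1 added alternative are not reported here. Values with ± in the text are SD for signal and SE for log2 differences.

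The alternatives fixed beforehand were median-of-ratios factors, total signal and cyclic loess as scalings, a stricter filter, fits of only the compared groups, sites off X, a test against a 1.5-fold change, pseudocounts of 0.5 and 5, a replicate block, and each library left out in turn. Alternatives added after seeing the data were fits within ATAC1 or ATAC2 (in ATAC2 untreated WT is 1 library and takes its spread from the other groups), the same with cyclic loess, library quality weights, the table without the Cd4 region, the 8 numbered libraries without a block, and camera after cyclic loess. Motif tests and a GC correction were not run because no genome sequence was at hand, and count-based tests were not run because the values are not counts. The filter on low values removed 0 sites, so the comparison with no filter was void.

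The model was tested on simulated data with 200 of 39657 sites changed. At 3 against 3 libraries it recovered 0%, 25.0% and 95.5% of changes of 1.5, 2 and 4-fold, with 0, 3 and 10 false calls. At 2 against 2 it recovered 0%, 0% and 91.0%, with 0, 0 and 14 false calls.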

Results

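Th17 cells are the helper T cells that make interleukin-17. Their chromatin was profiled by ATAC-seq after 3 days of culture from naive CD4+ T cells of mice lacking pyruvate dehydrogenase in T cells (KO) and of control mice (WT). Pyruvate dehydrogenase turns pyruvate into acetyl-CoA in mitochondria, and acetate is another source of acetyl-CoA. The series title ties the enzyme to a citrate pool that Th17 effector functions need. There were 3 KO and 3 WT untreated libraries, and 2 KO and 2 WT libraries from cells given 10 mM sodium acetate. Reads in sites were 10336677, 6581268 and 5972169 in the KO untreated libraries and 9034127, 9033536 and 9623689 in the WT untreated libraries. They were 3500172 and 13356560 in WT with acetate, and 11047781 and 5640663 in KO with acetate. Nothing in the labels says that replicates came from separate animals. The table of 39657 sites is taken as selected by the authors on these samples, since the sites are numbered as differential. The counts for untreated KO against WT are therefore not independent evidence of a difference. The comparison of KO with WT under acetate shares no library with that one.

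Summed over nuclear sites, signal was 6.19 ± 0.724 M (SD, n = 3) in untreated KO and 10.3 ± 1.15 M (n = 3) in untreated WT, a fold of 0.601. These sums rest on the authors' factor per library, whose making is not given in the sources used here: of the 6 untreated libraries KO untreated 1 had the most reads in sites and the lowest signal, 5.55 M. Signal was 8.94 ± 0.649 M (n = 2) in KO with acetate and 10.0 ± 1.00 M (n = 2) in WT with acetate. Neither genotype difference could pass an exact permutation test: p was 0.1 untreated, the smallest that 20 splits allow, and 0.667 with acetate, where 0.333 is the smallest. At the 2 mitochondrial sites signal was 104 ± 17.9 k in untreated KO and 38.7 ± 19.2 k in untreated WT (exact permutation p = 0.1). With acetate it was 24.97 ± 4.93 k in KO and 32.5 ± 15.4 k in WT. As a share of all signal in sites, which a factor per library cannot change, it was 1.18 to 2.01% in the untreated KO libraries. In the other libraries it was 0.201 to 0.658%. The first principal component of the log2 values held 70.0% of the variance and set the 3 untreated KO libraries apart from the other 7.

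**Figure D1:**
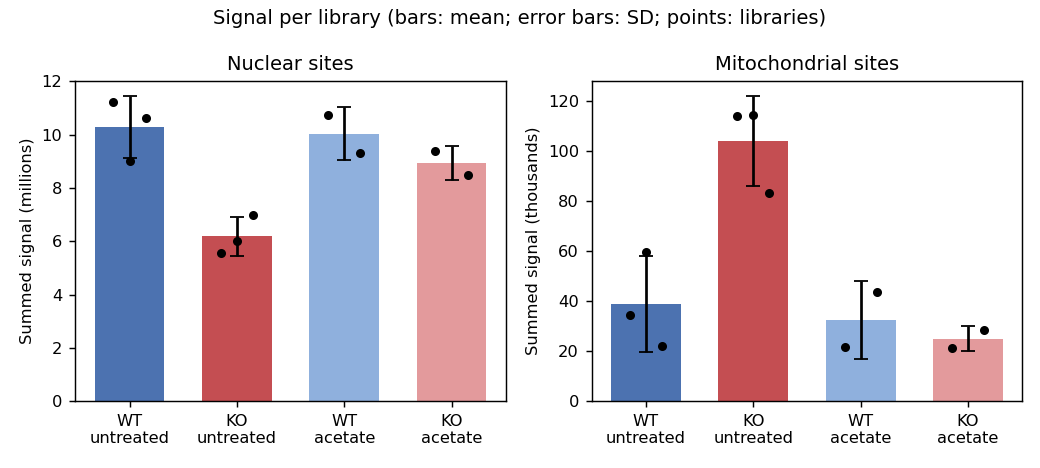
Summed signal per library at nuclear sites (left, M) and at mitochondrial sites (right, k), with bars for group means, error bars for SD and points for libraries (n = 3 untreated, n = 2 with acetate, per genotype). Nuclear signal in untreated KO lay at 6.19 ± 0.724 M against 10.3 ± 1.15 M in untreated WT, and mitochondrial signal at 104 ± 17.9 k against 38.7 ± 19.2 k.

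The first comparison asks how losing the enzyme changes open chromatin in Th17 cells. As deposited, untreated KO cells had lower signal than WT cells at most sites, Th17 loci included. At Pdha1, which encodes a catalytic subunit of the enzyme and is taken here as the floxed gene, the only site (X:160136288-160136488) fell to 56.0 ± 12.3 (n = 3) from 107 ± 15.9 (n = 3), a log2 difference of -0.94 ± 0.26 (adjusted p = 0.000753). That site does not test for the deletion, and its difference was close to the median of all sites, -0.84. At Il17a, which encodes the signature Th17 cytokine, all 7 sites fell, and the site at 1:20737033-20737233 went from 78.9 ± 18.6 in WT to 29.9 ± 9.80 in KO. Sites called higher were fewer, with rises at Cd4, whose regulatory sequence drives the Cre transgene, and at Aqp4.

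Of the 39657 sites, 3597 were higher and 35545 lower in untreated KO (limma, adjusted p under 0.05), with a median log2 difference of -0.84, a fold of 0.560. This direction depended on the scaling: the split was 3817 higher and 1323 lower with median-of-ratios factors, 3718 and 2276 with total signal, and 3708 and 956 with cyclic loess, whose medians were -0.04, -0.13 and 0.00. Of the 3597 sites called higher as deposited, 3595 were also called higher with cyclic loess, and 956 of the 35545 lower ones stayed lower. Cyclic loess moves the median from -0.84 to 0.00 and so raises the differences, which favours keeping the rises. Within the ATAC1 libraries alone (3 KO and 2 WT), 3516 sites were higher and 34736 lower.

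**Figure D2:**
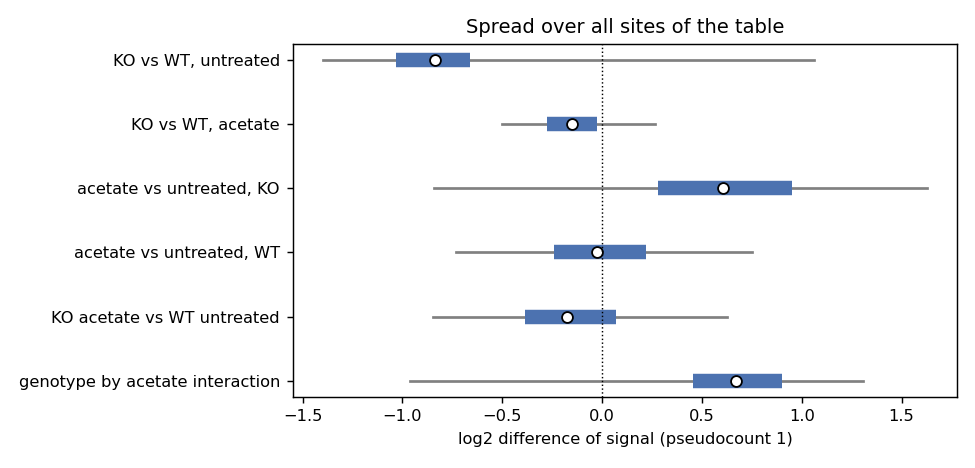
Log2 difference of signal over all 39657 sites for the 5 comparisons and the interaction, with the median (circle), the middle 50% of sites (thick line) and the 5th to 95th percentile (thin line). The median was -0.84 for KO against WT untreated, -0.15 with acetate, 0.61 for acetate in KO and -0.03 for acetate in WT.

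The Th17 loci fell with the rest of the table. Over Il17a, Il17f, Il23r, Il21 and Ccr6, 30 of 32 sites were lower and 0 higher as deposited, while with cyclic loess 2 were lower and 30 not called. Median log2 differences were -0.86 at Il17a, -1.02 at Il17f, -0.75 at Il23r, -0.82 at Il21 and -1.09 at Ccr6, and relative to the median of all sites these were -0.02, -0.18, 0.08, 0.01 and -0.26. Il23r encodes the receptor for interleukin-23. The sites that stayed lower with cyclic loess were at Il23r (6:67491830-67492030, 74.9 ± 16.1 in KO and 211 ± 32.9 in WT, log2 -1.49 ± 0.22) and at Ccr6 (log2 -1.70 ± 0.31), a chemokine receptor of Th17 cells. Il22 had no site in the table.

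**Figure D3:**
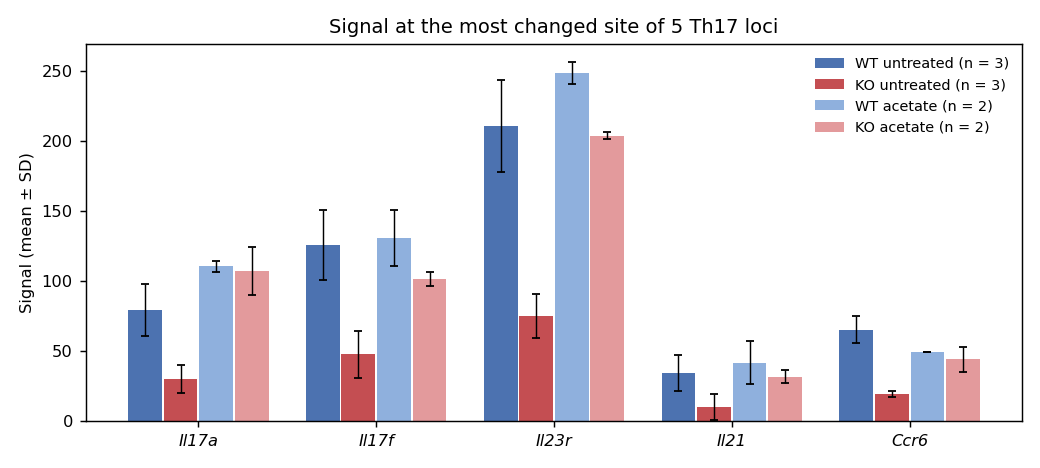
Signal (mean with SD) in WT and KO cells, untreated (n = 3 each) and with acetate (n = 2 each), at the site of 5 Th17 loci that differed most between untreated KO and WT. At Il17a signal was 29.9 ± 9.80 in untreated KO, 78.9 ± 18.6 in untreated WT, 107 ± 17.2 in KO with acetate and 110 ± 3.78 in WT with acetate; with cyclic loess the untreated differences at Il23r and Ccr6 were called and those at the other 3 loci were not.

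Loci of other T cell fates also fell. All 4 sites at Tbx21, the Th1 master regulator, were lower, as were all 11 at Gata3, the Th2 regulator, all 9 at Il2ra, all 17 at Tcf7 and the single site at Foxp3, the regulatory T cell factor; with cyclic loess none of these 42 sites was called. At Ifng 3 of 5 sites fell and 1 rose, and with cyclic loess 1 was lower and 1 higher. Acly, which makes acetyl-CoA from citrate, fell at both of its sites, and Acss2, which makes acetyl-CoA from acetate, at its single site (log2 -0.68 ± 0.28); with cyclic loess neither was called and Acss2 turned to 0.25.

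Among sites of at least median mean log2 signal whose groups did not overlap, the largest falls were at Plb1 (log2 -2.23 ± 0.23), Pecam1, an adhesion molecule (-2.21), Gadd45g (-2.10), Gm10277, Als2cl, D630003M21Rik, Acvrl1, Grk5, Ttc30a2 and Zbtb12, and all but Acvrl1 stayed lower with cyclic loess. Acvrl1 varied widely, at 446 ± 513 in WT. The largest rises were at Aqp4, a water channel gene (400 ± 83.0 in KO and 97.4 ± 28.9 in WT, 4.15-fold), Cd4 (3.51-fold), Arhgap25 (3.10-fold), Dmc1, a meiotic recombinase (2.99-fold), and Gfpt1, the first enzyme of hexosamine synthesis (2.96-fold). Alk, Lemd3, Fscn1, Myog and Fhod3 rose between 2.75 and 2.87-fold. All 10 rises stayed higher with cyclic loess, which raises the differences of this comparison as a whole and so favours rises.

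Sites that rose differed in kind from those that fell. Their median signal was 36.2 in WT and 82.4 in KO, against 196 and 104 at sites that fell. Near a gene end lay 143 of the 3597 (3.98%) and 9496 of the 35545 (26.7%), an odds ratio of 0.114 (Fisher's exact test, 95% interval 0.0952 to 0.135, across sites, which are not independent replicates). The share of sites called higher was 26.5% in the fifth with the lowest mean signal and 0.403% in the fifth with the highest.

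Most gene lists fell as the table did, and relative to the other sites 2 of 22 lists passed camera. The Th17 programme had 7 sites higher, 170 lower and 2 not called (7 and 170 adjusted over the list alone), with a median of -0.86 against -0.84 elsewhere (adjusted p = 0.320). With cyclic loess 7 of its sites were higher and 8 lower. Members with the smallest p were Batf (4.76-fold higher), a transcription factor of Th17 cells, and Lif, Runx1 and Rora, which fell to 0.346, 0.342 and 0.377-fold. Each value is of 1 site: all 23 measured genes of the list, Batf included, had a site called lower. In the Th1 list 6 sites rose and 85 fell, with Gzmb (log2 -1.49), Il12rb2 (-1.29) and Runx3 (-1.20) among the falls, and in the Th2 list 4 rose and 50 fell, with Il4ra (-1.22) and Ccr4 (-1.28). The regulatory T cell list had 1 site higher and 101 lower, with Ctla4 at -1.34 and Tnfrsf4 at -1.64 (adjusted p = 0.0575). T cell activation had 3 higher and 158 lower, with Fosl2 at -1.75 and Egr2 at -1.92 (adjusted p = 0.0575). With cyclic loess 10 activation sites were lower and 3 higher. That list and the regulatory one then passed, at an adjusted p of 0.0105 and 0.0325. With an estimated correlation, run on the deposited scale, both stood at 0.919, as did every list.

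In the naive and memory programme 6 sites rose and 284 fell, with Cd27 at -1.55 and Lef1 at -1.49. Inhibitory receptors had 5 higher and 77 lower. The Lag3 site at 6:124900561-124900761 rose 2.58-fold while the other sites nearest to Lag3 fell, and Tigit fell to 0.432-fold. Glycolysis had 2 higher and 70 lower, with the glucose transporter Slc2a1 at -1.19. Pyruvate dehydrogenase and TCA cycle genes had 4 higher and 70 lower, with Pdhx at -1.51. Citrate export, acetyl-CoA and fatty acid synthesis had 3 higher and 53 lower, with Scd1 at -1.63. Cholesterol synthesis had 1 higher and 39 lower, with Srebf2, its main regulator, at -1.39. Histone acetyltransferases and deacetylases had 11 higher and 88 lower, where Hdac9 rose 3.32-fold and Hdac4 fell to 0.247-fold. The stress response list had 1 higher and 42 lower (Ddit4, -1.66), the NRF2 list 2 and 41 (Gclc, 1.15), the interferon list 3 and 19, the cell cycle list 0 and 59 (Ccne1, -2.37) and the apoptosis list 5 and 83. All 15 measured genes of the NRF2 list, Gclc included, had a site called lower. For none of the 12 lists of this paragraph did the adjusted p lie under 0.05. With cyclic loess sites called lower numbered at most 9 in any of them. Adjusted over the list alone, the counts of these lists and of the Th1, Th2 and activation lists were the same, and the regulatory T cell list had 102 sites lower. The histone, interferon and NK lists tested above the other sites although their medians and means were negative.

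The 2 lists that passed hold markers of other lymphocytes. B cell markers had 8 sites higher and 11 lower of 21 (8 and 11 adjusted over the list alone), with an adjusted p of 7.88e-06. Their median was -0.70 while their mean was 0.09. Pax5, a B cell transcription factor, rose 3.88-fold, Blk, a kinase shared with some gamma-delta T cells, 4.75-fold and Blnk, a B cell adaptor, 2.11-fold, whereas Ebf1, another B cell factor, fell to 0.289-fold. Gamma-delta T cell markers had 5 higher and 7 lower of 12 (5 and 7 adjusted over the list alone), with an adjusted p of 0.00451. Their median was -0.58 and their mean 0.00. Blk and Sox4 (2.35-fold) rose, and Sox13 (log2 -1.14) and Cd163l1 (-0.86) fell. Both calls were lost at an adjusted p of 0.919 with an estimated correlation, which gave all 22 lists that value and so does not tell them apart. CD8 T cell markers had 0 higher and 22 lower, myeloid markers 1 and 14 with Spi1 at -1.41, and NK and innate lymphoid markers 3 and 15, where Zbtb16 rose 3.71-fold, with the same counts adjusted over the list alone.

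The second comparison asks whether the genotypes still differ when both receive acetate. Few sites did, and they lay at Cd4 and in 1 stretch of chromosome 3. At the Cd4 site 6:124885264-124885464 signal was 3971 ± 605 (n = 2) in KO and 570 ± 3.05 (n = 2) in WT, 6.91-fold, and without acetate it was 2079 ± 336 (n = 3) and 642 ± 74.1 (n = 3), 3.22-fold. At 6:124879835-124880035 in Cd4 it was 418 ± 113 and 19.3 ± 7.48 with acetate, and 425 ± 65.6 and 18.1 ± 11.7 without. A site between Cd4 and Lag3, outside both gene bodies and nearest to Lag3, was at 1319 ± 58.2 in KO and 293 ± 35.6 in WT. Lag3 encodes an inhibitory receptor and lies next to Cd4. Pdha1 did not differ with acetate (log2 0.12 ± 0.32, adjusted p = 0.993).

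With limma, 9 sites were higher and 0 lower of 39657, and 914 had an unadjusted p under 0.05. The 9 were 6 sites at Cd4 (log2 2.32 to 4.39), the Lag3 site (2.17 ± 0.24, adjusted p = 8.76e-13) and a pair of sites on chromosome 3. The lowest adjusted p of any other site was 0.188. In the ATAC2 libraries alone 11 sites were higher and 3 lower. Without the library WT acetate 2 the count was 34. Without the Cd4 region, 2 sites were past the threshold. The median log2 difference was -0.15 as deposited and 0.00 with cyclic loess, which left 9 higher and 0 lower.

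Within 50 kb of Cd4 there were 20 sites, and 7 were called higher with and without acetate. The other 13 were all called lower in untreated KO (median -1.05), with 0 called under acetate (median -0.22). A site at 6:124895903-124896103, between the Cd4 sites and the Lag3 site that rose, had a log2 difference of -0.95 untreated and -0.17 with acetate.

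**Figure D4:**
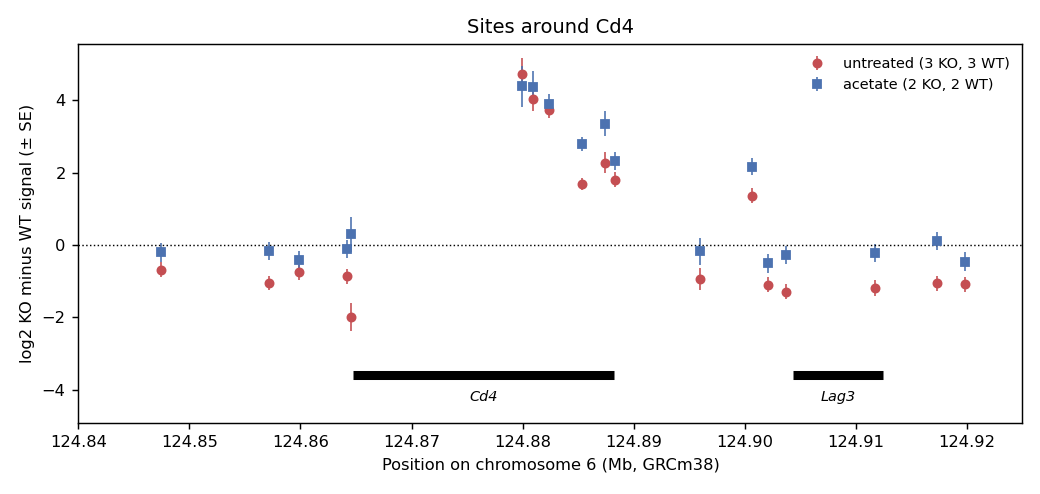
Log2 KO minus WT signal (± SE) at sites around Cd4 on chromosome 6 against position (Mb, GRCm38), untreated (circles, 3 KO and 3 WT libraries) and with acetate (squares, 2 and 2), with genes as black bars. The 7 sites called higher under both treatments ranged from 1.37 to 4.72 untreated and from 2.17 to 4.39 with acetate, while the site at 124895903 among them lay at -0.95 and -0.17.

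On chromosome 3, 19 neighbouring sites between 60362817 and 61037280 (674.5 kb), at Mbnl1, a splicing regulator, and P2ry1, a nucleotide receptor, were all called higher in untreated KO. This stretch was picked after the values were seen. With acetate, 3:60790238-60790438 stood at 69.2 ± 16.7 in KO and 9.04 ± 4.09 in WT (log2 2.85 ± 0.48), and 3:60795381-60795581 at 99.1 ± 33.5 and 7.42 ± 2.56 (3.56 ± 0.52). The other 17 were not called under acetate, and all 17 had a log2 difference above 0, with a median of 0.54 against -0.15 for all sites. No window of as many sites elsewhere had as high a median, the highest of 39303 being 0.41. Of 65 other runs of at least 5 sites called higher in untreated KO, 2 did. Over the 19 sites, which were called higher in untreated KO, the median as deposited was 0.99 untreated and 0.60 with acetate.

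**Figure D5:**
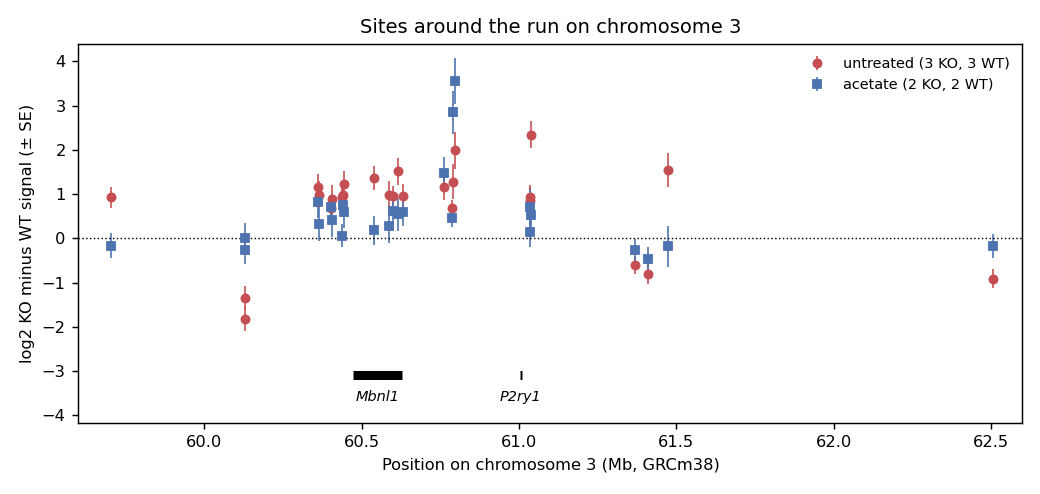
Log2 KO minus WT signal (± SE) at sites of chromosome 3 against position (Mb, GRCm38), untreated (circles, 3 KO and 3 WT libraries) and with acetate (squares, 2 and 2), with Mbnl1 and P2ry1 as black bars. The 19 sites from 60362817 to 61037280 were all higher in untreated KO, and the 17 of them not called with acetate had a median of 0.54 there.

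At the Th17 loci no site was called under acetate: 0 of 32 over the 5 loci, with medians of -0.28 at Il17a, -0.27 at Il17f, -0.32 at Il23r, -0.23 at Il21 and -0.17 at Ccr6. Those at Ifng, Tbx21, Gata3, Foxp3, Il2ra, Tcf7, Acss2 and Acly were -0.16, -0.03, -0.18, -0.59, -0.20, -0.16, -0.08 and -0.03. In the gene lists, 1 site was called, in the inhibitory receptor list, and 0 in the other 21, also adjusted over the list alone. It is the site between Cd4 and Lag3, counted there because Lag3 is its nearest gene. The lists' smallest adjusted p was 0.118, for the Th17, Th1, naive and memory, and gamma-delta lists, and with an estimated correlation all were 0.946 or above. The gamma-delta list tested above the other sites, with a median of -0.03 and a mean of 0.04. With 200 of 39657 sites changed, the self-test at 2 against 2 libraries recovered 0% of differences of 1.5 and 2-fold. It does not speak for changes shared by many more sites.

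Across all sites the genotype effects with and without acetate had a Pearson r of 0.337 and a Spearman rho of 0.186, across sites that are not independent replicates. With cyclic loess r was 0.310. Of sites called lower in untreated KO, 82.5% were also below 0 with acetate (51.3% with cyclic loess), and 58.5% of those called higher were above 0 (71.6% with cyclic loess). The 75th percentile of all sites was -0.03 with acetate as deposited. The interaction asks whether the genotype effect itself changed with acetate. It was called positive at 7728 sites and negative at 1431 as deposited, and at 55 and 2919 with cyclic loess, 79 and 2600 with median-of-ratios factors, and 111 and 2179 with total signal. At the Th17 loci 8 of 32 sites were called and all 8 lay above 0, but 0 were called with any of the 3 other scalings. The count rested on single libraries and was 501 without KO acetate 1. Every acetate library is ATAC2 and every untreated KO library ATAC1, so the interaction cannot be told apart from a prefix offset that differs between genotypes.

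The third comparison asks what acetate does in KO cells. Signal was higher with acetate at most sites, and Il2, the gene of the T cell growth factor interleukin-2, rose: its site at 3:37157120-37157320, 31.2 kb from the gene, went from 69.9 ± 21.0 (n = 3) to 355 ± 20.8 (n = 2), 5.18-fold. Il17a rose at 4 of 7 sites, and the site at 1:20737033-20737233 went from 29.9 ± 9.80 to 107 ± 17.2, 3.62-fold. Pdha1 did not pass (log2 0.22 ± 0.29, adjusted p = 0.509; -0.54 with cyclic loess, adjusted p = 0.0795). Sites at Zbtb34, Gbp8 and Gfpt1 fell by 2.32, 1.91 and 1.87 log2.

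Of 39657 sites 21657 were higher and 2357 lower (limma), with a median of 0.61, a fold of 1.52. The split was 5265 and 6323 with median-of-ratios factors, 6856 and 4991 with total signal, and 4567 and 6625 with cyclic loess. All 3 untreated KO libraries carry the ATAC1 prefix and both acetate ones ATAC2, so acetate and prefix were confounded in KO cells and no within-batch value exists. Without KO acetate 1 the count fell to 12825. This comparison also shares the untreated KO libraries with the first, which alone gives opposite signs.

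Among sites of at least median mean log2 signal whose groups did not overlap, the largest rises next to Acvrl1 (7.31-fold, called with wide spread and not with cyclic loess) included Cmip (6.66-fold), Dnajc11 (6.63-fold), Lzts1, Rab11fip4, S1pr3, Il2, Ubash3b, a negative regulator of T cell receptor signals, and Qser1. The largest falls there continued with Fndc1, Cdkal1, Dmc1, Arhgap25, Rora, a Th17 transcription factor (0.333-fold), Tyro3 and Hivep3. All 10 falls and 8 of these 9 rises were also called with cyclic loess, which lowers the differences of this comparison as a whole and so favours falls.

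Over the 5 Th17 loci 19 of 32 sites were higher and 0 lower, and with cyclic loess 4 were higher and 5 lower. Medians were 1.14 at Il17a, 0.90 at Il17f, 0.67 at Il23r, 0.86 at Il21 and 0.42 at Ccr6. Relative to the median of all sites they were 0.54, 0.29, 0.06, 0.26 and -0.19. Il23r at 6:67491830-67492030 rose 2.73-fold, from 74.9 ± 16.1 to 204 ± 2.37. Of the other fixed loci, Gata3 rose at 7 of 11 sites, Tcf7 at 8 of 17, Il2ra at 4 of 9, Ifng at 3 of 5 with 1 fall, Tbx21 at 2 of 4, Cd4 at 3 of 8, and Acly at 1 of 2 (3.09-fold). Foxp3 (log2 0.35) and Acss2 (0.64) did not pass, and with cyclic loess they were at -0.42 and -0.13.

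Against the other sites, 4 lists passed camera. T cell activation had 122 sites higher, 2 lower and 39 not called (124 and 2 adjusted over the list alone), a median of 0.91 against 0.61 elsewhere and an adjusted p of 0.00127. Its members Il2 (5.18-fold), Bhlhe40 (4.30-fold), Nfkb1 (4.35-fold) and Nfatc1 (4.37-fold) rose, and with cyclic loess 43 sites were higher and 8 lower. CD8 T cell markers had 18 higher and 0 lower of 22 (19 and 0 adjusted over the list alone, adjusted p = 0.0299), with Runx3, a transcription factor of CD8 and Th1 cells (4.76-fold), Crtam (2.47-fold) and Prf1, the pore-forming perforin (1.98-fold). B cell markers were lower than other sites, with 7 higher and 6 lower of 21 (7 and 6 adjusted over the list alone, adjusted p = 0.00127), a median of 0.38 and a mean of -0.08. Sites at Pax5, Blnk and Blk fell to 0.159, 0.438 and 0.297-fold and Ebf1 rose 5.59-fold. Gamma-delta markers had 2 higher and 2 lower of 12 (2 and 1 adjusted over the list alone, adjusted p = 0.0255), with a median of -0.00 and a mean of 0.00, Sox13 up and Blk down. All 4 calls were lost at an adjusted p of 0.986 with an estimated correlation, the value it gave all 22 lists.

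In the other lists, sites higher and lower were 99 and 6 of 179 for Th17, 64 and 4 of 93 for Th1, 31 and 3 of 54 for Th2, 54 and 1 of 103 for regulatory T cells, and 165 and 3 of 292 for naive and memory cells. They were 56 and 3 of 85 for inhibitory receptors, 49 and 2 of 72 for glycolysis, 39 and 3 of 75 for pyruvate dehydrogenase and TCA cycle, 27 and 3 of 56 for citrate export and fatty acid synthesis, 24 and 0 of 41 for cholesterol synthesis and 48 and 7 of 102 for histone acetyltransferases and deacetylases. The stress response list had 23 and 0 of 43, NRF2 31 and 0 of 44, interferon 11 and 1 of 23, cell cycle 33 and 0 of 59, apoptosis 51 and 5 of 89, myeloid markers 8 and 1 of 16, and NK markers 11 and 1 of 18. None of these lists passed, with adjusted p of 0.253 or above. Among their members, Foxo3 (7.02-fold), Hk1, a hexokinase (7.23-fold), Pmvk of cholesterol synthesis (5.75-fold), Cxcr3 (6.27-fold) and Elovl6 of fatty acid synthesis (4.11-fold) rose, while Hdac9 fell to 0.234-fold and Pfkp, a phosphofructokinase, to 0.321-fold. Adjusted over the list alone the Th17 list had 99 and 5, and for the others each count was within 2 of the one given. The histone, interferon and apoptosis lists tested below the other sites although their medians and means were positive. With cyclic loess the Th17 list had 25 higher and 29 lower sites.

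The fourth comparison asks what acetate does in WT cells. Changes went both ways, with a median near 0. Fhod3, a formin gene, rose 3.10-fold, from 104 ± 8.14 (n = 3) to 324 ± 41.7 (n = 2), and Il2 2.13-fold, from 198 ± 9.81 to 423 ± 6.94 at its site. Ccm2 fell to 0.281-fold, from 294 ± 86.0 to 79.9 ± 4.19. At Pdha1 the log2 difference was -0.84 ± 0.29 (adjusted p = 0.0660).

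With limma 1155 sites were higher and 1199 lower, with a median of -0.03. The library WT untreated 4 is the lone untreated one in ATAC2, and within ATAC2 2231 were higher and 549 lower (2 libraries against 1, so the spread came from the other groups). Single libraries moved the count: it was 286 without WT acetate 1, 902 without WT acetate 2, 933 without WT untreated 1 and 4062 without WT untreated 4.

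Taking sites of at least median mean log2 signal whose groups did not overlap, the largest rises after Fhod3 were at Cmip (2.68-fold), Fndc1, Krt16, Nr1i2, Pde4d, a cAMP phosphodiesterase, Cd70, a co-stimulatory ligand (2.37-fold), Atp8b1 (2.37-fold), Ccl5, a chemokine (2.37-fold), and Igf2bp3. After Ccm2 the largest falls among them were at Mkln1 (0.304-fold), Lcn4, Art2b, Srp9, Sh2d3c, Cited4, Clec16a, Pgpep1l and Emsy. All 20 were also called with cyclic loess. At the 5 Th17 loci 0 of 32 sites were called, and with cyclic loess 1 was higher and 1 lower. Of the other fixed loci, Tbx21 fell at 1 of 4 sites (log2 -0.95 ± 0.31), Gata3 rose at 1 of 11 (0.81 ± 0.25), Il2ra fell at 1 of 9 (-0.74 ± 0.24) and 0 were called at Cd4, Ifng, Foxp3, Tcf7, Acss2 or Acly.

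T cell activation passed camera here too, with 7 sites higher and 1 lower of 163 (7 and 0 adjusted over the list alone), a median of 0.14 and an adjusted p of 0.0355, lost at an adjusted p of 0.995 with an estimated correlation. Bhlhe40 (1.79-fold), Nfkb1 (1.73-fold) and Nfatc1 (1.87-fold) rose with Il2. In the Th1 list 5 sites rose and 2 fell, with Ccl5 and Runx3 (2.20-fold) up, and in the Th17 list 4 rose and 3 fell, with Batf (3.49-fold) up and Runx1 (0.520-fold) down. Regulatory T cell genes had 0 higher and 5 lower, with Lrrc32 (0.290-fold) and Ctla4 (0.415-fold). Naive and memory genes had 1 and 7, inhibitory receptors 1 and 2, glycolysis 1 and 2, with Pfkfb3 at 0.237-fold, and pyruvate dehydrogenase and TCA cycle 2 and 5. Cholesterol synthesis had 3 and 0 (Pmvk, Mvk and Sc5d), histone acetyltransferases and deacetylases 3 and 4, NRF2 3 and 0, apoptosis 1 and 5, CD8 markers 2 and 0 and NK markers 2 and 0. The Th2 list and gamma-delta markers had 1 and 1 each, fatty acid synthesis 0 and 2, B cell markers 1 and 0, stress response and myeloid lists 0 and 1 each, and interferon and cell cycle 0 and 0. Apart from activation the adjusted p was 0.0900 or above. Adjusted over the list alone the Th1 list had 8 and 2 and cholesterol synthesis 3 and 2, and for the others each count was within 1 of the one given. Median and mean differed in sign for the Th17 list (-0.02 and 0.01) and the NRF2 list (-0.01 and 0.10), and lay within 0.05 of 0 where they did in other lists.

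The fifth comparison asks whether KO cells given acetate still differ from untreated WT cells. They did at Cd4 and at the site between Cd4 and Lag3: the Cd4 site at 6:124885264-124885464 was 6.17-fold higher and the site nearest to Lag3 4.84-fold. Mkln1 was at 67.2 ± 9.46 (n = 2) in KO with acetate and 286 ± 64.2 (n = 3) in untreated WT, a fold of 0.241. Pdha1 stood at 65.1 ± 15.3 and 107 ± 15.9 (log2 -0.72 ± 0.29, adjusted p = 0.115).

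Of 39657 sites 827 were higher and 2277 lower (limma), with a median of -0.17. The split was 1734 and 1384 with median-of-ratios factors, 1679 and 1129 with total signal, and 1699 and 1542 with cyclic loess, whose median was 0.02. Within ATAC2, again 2 libraries against 1 without a spread of its own for untreated WT, 917 were higher and 622 lower. The count was 765 without KO acetate 3, 927 without WT untreated 1, 954 without KO acetate 1 and 5873 without WT untreated 4.

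In sites of at least median mean log2 signal whose groups did not overlap, the largest rises after Cd4 and Lag3 were at Fhod3 (2.94-fold), Cd70 (2.85-fold), Clip4, Atp8b1, Nav1, Mbnl1 (2.27-fold), Slc24a4 and Pnkd. The largest falls there, after Mkln1, were at Vrk3 (0.269-fold), Dnah8, Ccm2, Kctd19, Srp9, Emsy, Gm52008, Gbp8 and H2bc6. All 20 were also called with cyclic loess. At the 5 Th17 loci 1 of 32 sites was lower, at Il21 (log2 -0.90 ± 0.24). Gata3 fell at 1 of 11 sites, Il2ra at 1 of 9, Acly rose at 1 of 2 (1.67-fold) and Cd4 at 6 of 8. No site was called at Ifng, Tbx21, Foxp3, Tcf7 or Acss2.

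No list passed camera here, with an adjusted p of 0.179 or above and 0.926 with an estimated correlation. Regulatory T cell genes had 1 site higher and 14 lower (2 and 16 adjusted over the list alone), with Lrrc32 (0.330-fold), Itgae (0.466-fold) and Ctla4 (0.423-fold), and naive and memory genes 2 and 15, with Bcl2, a survival gene (0.362-fold), and Bach2 (0.501-fold). The Th17 list had 1 and 8, with Batf 3.13-fold higher and Hif1a at 0.521-fold, apoptosis 1 and 10, glycolysis 1 and 6, pyruvate dehydrogenase and TCA cycle 1 and 6, with Pdp1 at 0.397-fold, and histone acetyltransferases and deacetylases 1 and 5. The Th1 list had 4 and 2, Th2 0 and 3, activation 4 and 2, with Il2 4.90-fold higher at a site within the gene (3:37121125-37121325), inhibitory receptors 2 and 4, fatty acid synthesis 1 and 2, cholesterol synthesis 2 and 1, and NRF2 2 and 1. The stress response list and gamma-delta markers had 0 and 2 each, cell cycle and NK markers 0 and 1 each, CD8 markers 1 and 0, and interferon, B cell and myeloid lists 0 and 0. Adjusted over the list alone, each count was within 2 of the one given. Activation, at a median of -0.04 and a mean of -0.02, tested above the other sites, and B cell markers had a median of -0.10 and a mean of 0.01.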

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

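All tests of explanations in this part were chosen after the results had been seen.

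As deposited, the genotype by acetate interaction was called positive at 7728 sites and negative at 1431, against 55 and 2919 with cyclic loess. Every acetate library is ATAC2 and every untreated KO library ATAC1. The interaction therefore cannot be told apart from a prefix offset that differs between genotypes. It also contains the untreated genotype difference, on which the sites are taken as selected. Among sites of at least median mean log2 signal, the largest positive values, in log2, lay at Plb1 (1.94), Gfod1 (1.79), Grk5 (1.78), Gm10277 (1.71), Pecam1 (1.70), Cdadc1 (1.70), Parp3 (1.68), Slc41a2 (1.62), Inpp4b (1.62) and S1pr3 (1.61). The largest negative ones there included Aqp4 (-2.33), Arhgap25 (-2.11), Fscn1 (-1.82), Dmc1 (-1.77), Pced1b (-1.74), Gfpt1 (-1.68), Lemd3 (-1.63), Stk33 (-1.62) and Olfr1414 (-1.62). They stood out by the test of the difference itself. With cyclic loess all 9 negative ones were called and 5 of the 10 positive ones: Plb1, Grk5, Gm10277, Pecam1 and Parp3. That scaling lowers the interaction values as a whole, which favours the negative ones. At the 2 mitochondrial sites, outside the nuclear comparisons, signal in untreated KO was 2.88-fold that in untreated WT (exact permutation p = 0.1), and 0.807-fold with acetate. Their mean share of site signal, free of the scaling, was 1.68% in untreated KO and 0.390% in untreated WT. Whether this goes with the background weighed below was not tested.

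Most sites had lower signal in untreated KO than in untreated WT, and sites at genes such as Aqp4, Dmc1 and Batf had higher signal. Batf also had a site called lower. The 3597 sites highest in any pair of a KO and a WT library were followed in the other 4 untreated libraries. There they lay at least 1.84 log2 above the median of all sites (median SE 0.227). The table is taken as selected on these same libraries, so this gap is no held-out check on a single wrong scaling factor per library. Of the 3597 sites called higher as deposited, 3595 were also called higher with cyclic loess. That scaling raises the differences as a whole, so these sites could hardly lose the call. For the lower sites such a factor stays open. With median-of-ratios factors 1323 were called lower, but this scaling sets the median to about 0 by itself. More background and less signal at open sites in the untreated KO libraries stays open. As it would give, 26.5% of the sites in the fifth of lowest signal and 0.403% in the highest were called higher. The median difference went the other way, at -0.97 in the former and -0.72 in the latter, but selection on these libraries may shape it. Sites were also grouped by signal in WT with acetate. The lowest group then fell more than the highest in 6 of 9 pairs of untreated libraries, all but those with WT untreated 4. A difference between ATAC1 and ATAC2 is argued against by 34736 lower sites within ATAC1, and an effect of the enzyme's loss stays open. The 10 splits of the 6 untreated libraries are too few for a share under 0.05 (38971 sites in the real split, the only 1 of that size, and 0 in the highest other).

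As deposited, signal at the sites lower in untreated KO, Il17a and Il2 among their genes, was higher in KO with acetate, by a median of 0.66. The direction depends on the scaling. Over all sites, acetate in KO gave 5265 higher and 6323 lower with median-of-ratios factors, and 4567 and 6625 with cyclic loess. An offset of the ATAC2 libraries that is equal in both genotypes, without an acetate effect, was not seen in WT. At the sites lower in untreated KO, ATAC2 and ATAC1 libraries of WT differed by -0.0111. In a simulation, unchanged sites selected as lower in untreated KO changed by -0.277 with acetate in WT. The simulation picked only unchanged sites with an unadjusted p under 0.05, while 35545 of 39657 sites are lower here. Its value cannot size what selection may hide, so such an offset stays open. Part of the rise in KO may be a return toward the mean of sites selected on the untreated libraries. Unchanged sites in the same simulation rose by 0.274, which cannot size that part for the same reason. The median rise was 0.66 at the lower sites and 0.61 over all sites, so picking the lower sites within the table changed it little. Selection of sites into the table was not simulated, so the share stays open. An effect of acetate stays open too and cannot be told apart from an ATAC2 offset in KO cells alone, as every KO acetate library is ATAC2.

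Sites at Cd4, a site nearest to Lag3 and the stretch of chromosome 3 at Mbnl1 and P2ry1 were higher in KO with and without acetate. Copies of Cd4 regulatory sequence in the Cre transgene are a candidate explanation at Cd4, where 7 of 20 sites within 50 kb were called higher in both. A gained segment stays open on chromosome 3: the 17 sites not called with acetate had a median of 0.54 there, against at most 0.407 in windows of as many sites elsewhere, and a gain alone would give a similar fold in both treatments, which over the 19 sites was 1.98 untreated and 1.52 with acetate as deposited but 3.54 and 1.69 relative to all sites. A rise that any higher site keeps in part stays open too: 0 of 10000 random draws of 17 such sites had as high a median (0.5 at most), but draws are scattered, and 2 of 65 other runs of such sites did, 1 of them 6 sites on chromosome 13 (103235871-103771469) with 0.63. An effect of genotype on transcription at either locus was not tested and stays open.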

How the results depend on the processing

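The fits within ATAC1 or ATAC2, library quality weights, the table without the Cd4 region, the 8 numbered libraries without a block and the list tests with cyclic loess were chosen after seeing the data, and the other alternatives before the data were examined. Within ATAC2 untreated WT is 1 library, whose spread was taken from the other groups. Where no cause is named, the cause was not tested.

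Sites named by the rule, called or not, were compared by call, and by direction where called. For KO against WT untreated all 116 kept both within ATAC1 and 60 with cyclic loess, where 53 lost the call and 3 turned. For acetate in KO 100 of 114 were unchanged with cyclic loess, and for acetate in WT 75 of 81 with cyclic loess and 48 within ATAC2. For KO with acetate against WT untreated 71 of 80 were unchanged with cyclic loess and 38 within ATAC2. With cyclic loess 14 of 19 interaction genes were, such as Aqp4 and Plb1, and 1 of 19 in a test against a 1.5-fold change. Pseudocounts moved no count of sites by over 1.5 times.

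For KO against WT untreated the count of 39142 was 5140 with median-of-ratios factors, 5994 with total signal, 4664 with cyclic loess and 6691 with cyclic loess within ATAC1. It was 19635 with the stricter filter, which tests fewer sites, and 5739 against a 1.5-fold change, which asks for more. Leaving out each library gave 35524 to 39128.

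With acetate the 9 sites at Cd4, Lag3 and chromosome 3 became 3 with the stricter filter, 15 with only the compared groups, 14 within ATAC2, 16 with weights and 2 without the Cd4 region. Leaving out libraries gave 8 to 34, with 34 without WT acetate 2 and 14 without WT untreated 4.

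For acetate in KO the 24014 sites became 11588, 11847 and 11192 with median-of-ratios factors, total signal and cyclic loess, 11611 with the stricter filter, and 5589 against 1.5-fold. Leaving out libraries gave 12825 (without KO acetate 1) to 25997.

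For acetate in WT the 2354 sites became 412 with the stricter filter, 733 with only the compared groups, 34 against 1.5-fold, 4140 with weights and 4009 within ATAC2 with cyclic loess. Leaving out libraries gave 286 (without WT acetate 1) to 4062 (without WT untreated 4), with 902 without WT acetate 2 and 933 without WT untreated 1.

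For KO with acetate against WT untreated the 3104 sites became 926 with the stricter filter, 103 against 1.5-fold, 1539 within ATAC2 and 7425 with weights. Leaving out libraries gave 765 (without KO acetate 3) to 5873 (without WT untreated 4), with 927 without WT untreated 1 and 954 without KO acetate 1.

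The 9159 interaction sites became 2679, 2290 and 2974 with the 3 scalings, 2925 with the stricter filter, 24 against 1.5-fold and 28086 with weights. Leaving out libraries gave 501 (without KO acetate 1) to 17884 (without WT untreated 2). It was 1321 and 2267 without KO untreated 1 and 2, 2053 without WT untreated 1, 5089 and 1695 without WT acetate 1 and 2, and 4339 without KO acetate 3.

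The labels do not say whether replicate numbers pair the libraries. Correlations of same-number libraries across groups lay between -0.122 and 0.331. Those of different-number libraries lay between -0.331 and 0.122. The correlations used deviations from group means, which are opposite in a group of 2 libraries. Same-number and different-number values there mirror each other, so the ranges do not settle it. A block on the number, over 8 numbered libraries, gave 23 sites for KO against WT with acetate (11 without the block in the same 8), 6200 for acetate in WT (3818), 4297 for KO with acetate against WT untreated (2371) and 16771 for the interaction (10731). Lists past the threshold with the block were 6 for KO against WT untreated, 1 with acetate, 1 for acetate in KO and 0 for acetate in WT.

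Of the lists, such as activation and B cell markers, 2, 0, 4, 1 and 0 passed in the 5 comparisons. With an estimated correlation 0 passed in each of the 5 comparisons, at a camera adjusted p of 0.919 or above for every list. That setting therefore does not tell the lists apart. With sites within 1 kb of a gene end 0, 1, 1 passed in the first 3 comparisons and 1 for KO with acetate against WT untreated. With 1 site per gene 1, 3, 0, 0 and 1 passed. With cyclic loess 4 passed for KO against WT untreated. The correlation between genotype effects, 0.337, was 0.310 with cyclic loess.

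Direction turned at named sites that had been called, given in log2. In KO against WT untreated, the fit within ATAC1 with cyclic loess turned Pdha1 (0.09), Tbx21 (0.007), Gata3 (0.11), Acss2 (0.30), Ifih1 (0.091) and Cd14 (0.052). Acss2 also turned with median-of-ratios factors (0.11), total signal (0.026) and cyclic loess (0.25), as did Gzmk (0.004) and Cd14 (0.10) with cyclic loess. For acetate in KO, Gzmk turned with median-of-ratios factors (-0.033) and cyclic loess (-0.058), and Cd14 with cyclic loess (-0.074). In KO with acetate against WT untreated Il4ra reached 0.00 with cyclic loess within ATAC2.

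A GC correction, alone or with the block, motif tests and count-based tests were not run, and no filter against the filter was void, since it removed 0 sites. The number of libraries limits the comparison of KO and WT with acetate. At 2 against 2, with 200 sites changed, the self-test recovered 0% of 2-fold changes and 91.0% of 4-fold ones.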

Other observations

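Some sites changed with acetate in the same direction in both genotypes. Il2, Cmip, Atp8b1, Ccl5, Runx3, Nfkb1, Bhlhe40 and Pmvk each had a site that was called higher with acetate in both KO and WT cells, and of these the Il2 site rose 5.18-fold in KO and 2.13-fold in WT. In all, 819 sites were called higher in both genotypes, where 631 would be if the calls were independent, and 239 lower in both against 71.3. With cyclic loess these were 1152 against 202 and 1233 against 270. These comparisons share no library, though both set ATAC2 libraries against mostly ATAC1 ones, and their effects had a Pearson r of 0.484 and a Spearman rho of 0.574 across sites, which are not independent replicates. Of the sites called higher and lower in WT, 85.5% and 74.4% had the same sign in KO, where the 25th percentile of all sites was already 0.28. With the WT effect taken within ATAC2, against a single untreated library, r was 0.319 and these shares were 88.7% and 38.6%. Overlaps of calls in that fit rest on the single untreated WT library and are not weighed here.

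As deposited, 21560 of the 35545 sites lower in untreated KO were higher with acetate in KO, where 19411 would be if the calls were independent. Of the 3597 higher sites 2184 were lower with acetate, against 214. With cyclic loess 956 sites in all were lower in untreated KO, and 4567 in all were higher with acetate in KO. The comparisons share the untreated KO libraries, and the effects had an r of -0.799. Their covariance was -0.392, where sharing alone gave -0.0308 in simulated sites without an effect. Selection of sites into the table was not simulated. Sites higher in untreated KO had a median of 0.07 for KO against WT with acetate, and sites lower in untreated KO one of -0.16. With acetate in WT, 366 of the 3597 higher sites rose, Fhod3 and Batf among them. These comparisons share the untreated WT libraries, and r was 0.0393. The covariance was 0.0119, where sharing alone gave 0.0307 in the simulation, so the overlap is not evidence of a shared change. Of the 3597 higher sites, such as those at Aqp4, Batf and Pax5, 19.9% had no gene within 50 kb, against 6.92% of the lower ones. In 1341 of the 3597 (37.3%) the mean signal in untreated KO was above 104, the median of the lower sites in KO.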
